A study of Mus musculus with 6 samples.

How the data were processed

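Gene expression was measured on 6 Affymetrix oligonucleotide arrays, each hybridised with RNA from haematopoietic stem cells (HSCs) of mouse bone marrow. Per the labels, 3 arrays came from mice without Irgm1 (older name Lrg-47), an immunity-related GTPase that interferons induce, and 3 from wild-type mice. The mice were C57BL/6 aged 8 to 12 weeks, kept free of specific pathogens. The cells were sorted by dye efflux as the side population, with staining for Sca-1, c-kit and lineage antigens. Per the labels' protocols, the RNA was amplified linearly in 2 rounds of T7 transcription and labelled with biotin. Such amplification favours the 3' ends of transcripts, so the distance between 3' and 5' control probe sets was examined on each array.

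The values the authors deposited are expression values per probe set on the log2 scale, made with GCRMA per the submitters' processing notes. GCRMA corrects the background of each probe from its sequence, normalises between arrays and summarises the probes of a set. Its version and settings are not given in the sources used here, and the log2 scale was read from the values themselves. The correction leaves probe sets without signal in a narrow band of low values, so folds of dim genes depend on that correction. The deposited values were used as they stood, with no pseudocount and no further normalisation.

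Each array held 45101 probe sets. In the platform table, 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none. Gene names were given only to probe sets with 1 symbol, and 34754 probe sets matched a gene identifier of the RefSeq gene table of assembly GRCm38.p6. That table served for names and gene order only, and no coordinates are given because the sources used here name no genome build for the arrays.

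Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend and a single coefficient for the knockout label minus wild type. Tests were 2-sided, and p-values were adjusted by the method of Benjamini and Hochberg. A probe set was tested when it lay above the array's median in at least 3 of the 6 arrays, whatever the group, and was not an Affymetrix control. This left 22580 probe sets, of which 18529 had 1 symbol, for 10374 genes. Adjusted p under 0.05 was the threshold. All adjusted p-values of single genes are from this limma fit. Differences are on the log2 scale with their standard errors (SE), and levels are means ± SD of 3 arrays. A fold is given as a lower bound where a group lay, on every array, at or below the highest value of the control probe sets for bacterial transcripts (Dap, Lys, Phe, Thr and Trp), which ranged from 3.00 to 3.18.

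Of 28 gene lists written before the data were examined, 26 were tested with limma's camera. Each gene was represented by its tested probe set with the highest mean, and the correlation between genes was preset at 0.01. The p-values were adjusted over the lists. Members were also counted one by one, over all probe sets tested and adjusted over the list alone. The list of mast cell and basophil markers had 4 tested members, under the minimum of 5, and sex-linked genes were described per group. Genes to be named were fixed beforehand as Irgm1, the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, and up to 4 members of each list with the smallest p, with sex-linked genes. Other genes are named only where the text says that they were chosen after their values were seen.

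The groups, the tests, the lists and most alternatives were fixed before the data were examined. The alternatives were other filters on dim probe sets, quantile normalisation or median centring, other variance models, array weights, the replicate number as a block, leaving out each array, other thresholds, other ways of choosing probe sets, camera with an estimated correlation, and limma's rotation test fry. A fit with the actin 3' to 5' gap as a covariate, a list of imprinted genes and lists of T cell receptor and NK receptor genes were added after the data were seen. The genes called T cell receptor genes were Cd3d, Cd3e, Cd3g, Cd247, Cd28, Cd5, Cd6, Lat and Zap70. They are CD3 subunits and other surface and signalling genes of T cells, without the receptor's alpha and beta chains. The pseudocounts listed for linear values did not apply.

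The fit was tested on simulated data with the measured means and spreads of the 22580 probe sets, 200 of them changed. It called 34% of 2-fold and 83% of 4-fold changes, all with the right sign, and 4.1% of its calls were unchanged probe sets. One list was shifted in the simulation and passed, and 0 unshifted lists did. This does not give the rate of false passes in the measured data, where splits that mixed the groups passed up to 10 lists. Such splits keep part of any difference between the groups, so they do not give that rate either. The number of arrays, 3 per group, limits the precision. The labels do not say that the arrays of a group came from separate animals or pools, so the p-values measure only the spread between these samples, which may be partly technical. Pearson correlations across probe sets, which are not independent replicates, were 0.991 to 0.995 between arrays of a group and 0.987 to 0.992 between groups, and no arrays were duplicates.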

Results

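Haematopoietic stem cells sorted from bone marrow of mice labelled Irgm1−/− were compared with those of wild-type mice, with 3 arrays per group. The design asks which transcripts differ in stem cells that lack this interferon-induced GTPase. The median of the log2 expression values lay between 3.67 and 3.73 on the 6 arrays. The gap between the 3' and 5' actin control probe sets, a sign of how much of each transcript the amplified RNA covered, was 2.86, 2.81 and 3.56 on the knockout-labelled arrays and 3.16, 3.16 and 2.57 on the wild-type arrays, so the groups overlapped. Replicate 3 of each group lay farthest from the other arrays of its group in this gap.

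The level of Irgm1 itself was read first. Its single probe set gave 7.68, 8.58 and 7.84 on the knockout-labelled arrays and 8.39, 8.57 and 8.36 on the wild-type arrays, a log2 difference of −0.41 (SE 0.25, adjusted p = 0.475). The transcript was thus detected well above the control probe sets in both groups. The labels do not give the deleted part of the gene, so a probe set outside it checks nothing about the genotype. The groups are therefore named below by their labels.

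Some interferon-stimulated genes, genes of the cell cycle and markers of T and NK cells rose on the arrays labelled Irgm1−/−, and several imprinted transcripts fell. Of the lists, 16 of 51 antiviral, 8 of 54 replication and 15 of 63 mitosis genes and 5 of 14 T and NK cell markers rose and 1 mitosis gene fell, and none of these 4 lists passed with an estimated correlation between genes (adjusted p = 0.264, 0.0836, 0.0836 and 0.346). The chemokine Ccl5, one of the T and NK cell markers, rose 30.5-fold, from 8.10 ± 0.70 to 13.03 ± 0.42 (SD, n = 3 each), and the antiviral genes Ifit1 and Usp18 rose 17.1-fold and 7.87-fold. The imprinted long noncoding RNA Meg3 fell from 10.78 ± 0.06 to 5.06 ± 0.73 (SD, n = 3 each), a log2 difference of −5.73 (SE 0.34, adjusted p = 0.000914). The proliferation marker Mki67 rose 3.31-fold and cyclin A2 (Ccna2) 3.86-fold.

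In all, 150 probe sets were higher and 163 lower among 22580 tested, for 123 and 116 named genes, and 36 of these probe sets had no single gene symbol. At least 2-fold differences were found for 136 of the higher and 129 of the lower probe sets. The 3 arrays of one group lay wholly above or below those of the other for 22.6% of tested probe sets, where chance gives 10%. The counts fell when single arrays were left out, which also leaves fewer arrays, and fell least without knockout-labelled replicate 3. They were 45 higher and 40 lower without knockout-labelled replicate 1, 53 and 46 without replicate 2, 23 and 37 without wild-type replicate 1, 17 and 28 without wild-type replicate 2 and 77 and 82 without wild-type replicate 3, and without any filter on dim probe sets they were 49 and 54. The naming rule selected 45 genes past the threshold, of which 20 lost the call without knockout-labelled replicate 1, 17 without replicate 2, 9 without replicate 3, and 27, 31 and 13 without wild-type replicates 1, 2 and 3. With no filter on dim probe sets 18 of the 45 lost it, with a filter at the 25th percentile 13 and with the replicate block 22. Ccl5, Cxcl9, Cxcl10, Rsad2, Phf11d, Ifi27l2a, Usp18, Ccna2, Meg3, Rian, Ndn, Ntf5 and Trib2 were past the threshold in every alternative that tested them.

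**Figure D1:**
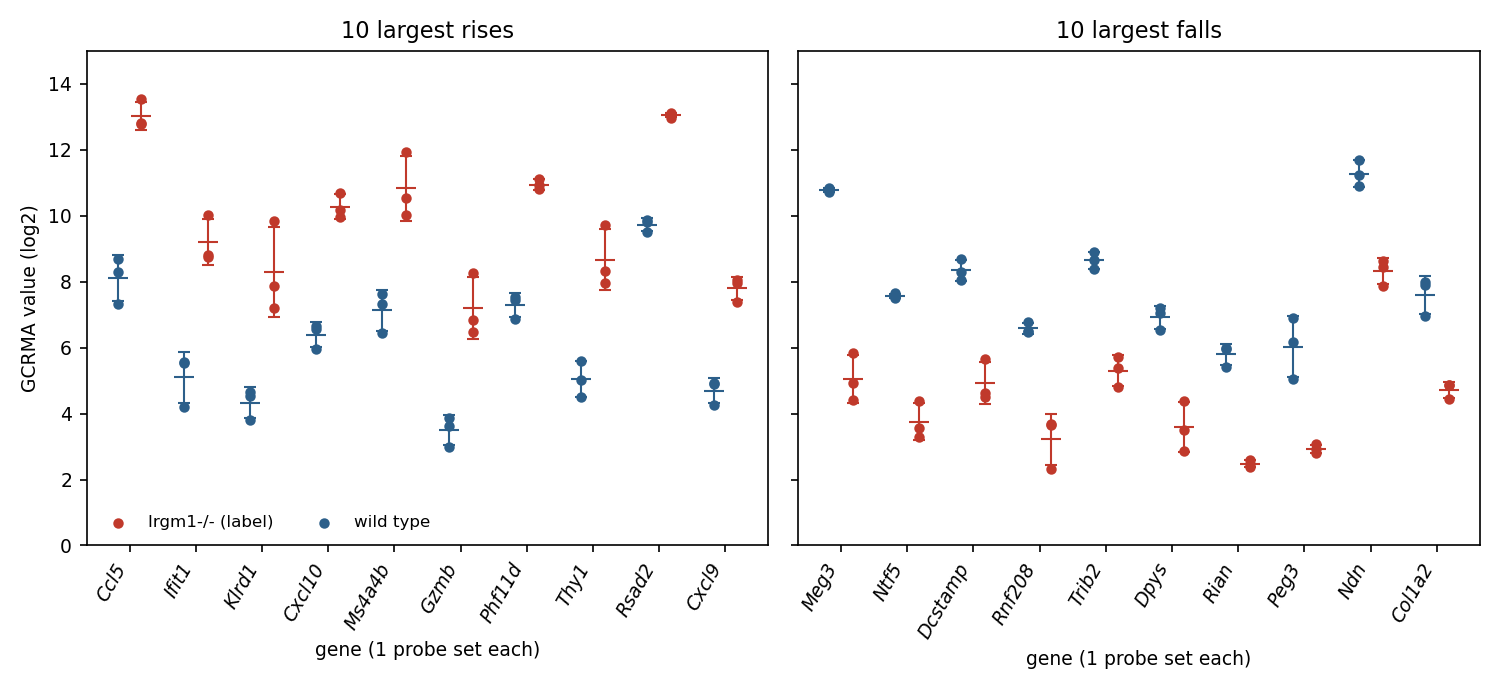
Log2 GCRMA values of the 10 genes with the largest rise and the 10 with the largest fall, 1 probe set per gene, on the x axis by gene. Dots are single arrays, bars the mean ± SD of 3 arrays labelled Irgm1−/− (red) or wild type (blue), and the groups of each gene do not overlap, as for Ccl5 (13.03 against 8.10) and Meg3 (5.06 against 10.78).

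Some interferon-stimulated antiviral genes rose on the arrays labelled Irgm1−/−. Of 51 tested interferon-stimulated antiviral genes, 16 rose, 0 fell and 35 did not pass, and 27 rose and 1 fell when adjusted over the list alone. Rsad2, which encodes the antiviral protein viperin, reached 13.05 ± 0.07 against 9.72 ± 0.19 (log2 difference 3.33, SE 0.13, adjusted p = 0.000214). Phf11d rose by 3.66 (SE 0.21, adjusted p = 0.00089), Ifi27l2a by 2.79 (SE 0.26, adjusted p = 0.00533) and Usp18, which restrains interferon receptor signalling, by 2.98 (SE 0.29, adjusted p = 0.00737). Ifit1 rose by 4.10 (SE 0.47, adjusted p = 0.0118). The mean difference of the list was 0.97 (camera adjusted p = 1.35e-17), whereas its adjusted p was 0.264 with an estimated correlation and 0.0131 by fry.

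Of 10 tested interferon-inducible GTPases, the protein family of Irgm1 and its relatives, 2 rose, 0 fell and 8 did not pass, and 3 rose when adjusted over the list alone. Gbp3 rose by 1.09 (SE 0.12, adjusted p = 0.009) and Gm4951 by 1.54 (SE 0.26, adjusted p = 0.0453). Gbp7 differed by 0.89 (adjusted p = 0.111) and Iigp1 by 0.92 (adjusted p = 0.263). These counts and values rest on the probe set with the highest mean. The 1 other tested probe set of Iigp1 was called higher. The list's mean difference was 0.51 (camera adjusted p = 0.00556). Its adjusted p was 0.594 with an estimated correlation and 0.186 by fry, and without knockout-labelled replicate 2 the mean was 0.37 (camera adjusted p = 0.0661), the adjusted p over its alternatives ranging from 0.000171 to 0.594. Gbp3 lost the call without wild-type replicate 1 or 2 and Gm4951 without any 1 array, with adjusted p of up to 0.0577 and 0.147.

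Among 28 tested genes of interferon gamma signalling and its targets, 4 rose, 0 fell and 24 did not pass, and 4 rose when adjusted over the list alone. The chemokines Cxcl10, Cxcl9 and Cxcl11, which attract activated T cells through a shared receptor, rose by 3.88 (SE 0.27, adjusted p = 0.00157), 3.09 (SE 0.27, adjusted p = 0.00385) and 2.45 (SE 0.36, adjusted p = 0.0299). The inflammatory caspase Casp1 rose by 0.99 (SE 0.16, adjusted p = 0.0345). Casp1 lost the call without any 1 array and Cxcl11 without knockout-labelled replicate 1 or any 1 wild-type array, with adjusted p of up to 0.128 and 0.125. The median of the list was 0.05 and its mean 0.39, and the list did not pass (camera adjusted p = 0.0821). It passed without wild-type replicate 1 (mean 0.44, camera adjusted p = 0.018), and over its alternatives the adjusted p ranged from 0.018 to 0.594. Of 23 genes of antigen processing and MHC, 1 rose and 1 fell, also when adjusted over the list alone. Psmb9, an immunoproteasome subunit, rose by 0.82 (SE 0.13, adjusted p = 0.0345), and H2-Ob, which modulates peptide loading of class II molecules, fell by 1.09 (SE 0.16, adjusted p = 0.0279). Psmb9 lost the call without any 1 array and H2-Ob without any 1 but knockout-labelled replicate 3, with adjusted p of up to 0.132 and 0.114. The list lay at the threshold (mean 0.21, camera adjusted p = 0.0498). Its adjusted p was 0.594 with an estimated correlation, and the list did not pass without knockout-labelled replicate 2 (mean 0.16, adjusted p = 0.186), knockout-labelled replicate 3 (0.15, 0.204), wild-type replicate 2 (0.24, 0.0714) or wild-type replicate 3 (0.12, 0.124), within a range of 0.00337 to 0.594 over its alternatives. Some markers of T and NK cells were higher on the same 3 arrays (5 of 14 tested genes called, mean difference 2.24), a list that did not pass with an estimated correlation (adjusted p = 0.346) or by fry (0.0893). Without knockout-labelled replicate 3, where T cell receptor genes were highest, the mean of the antiviral list was 0.94 and that of the GTPases 0.51.

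Some genes of the cell cycle also rose on the arrays labelled Irgm1−/−. Of 54 tested genes of DNA replication and G1/S, 8 rose, 0 fell and 46 did not pass, and 36 rose when adjusted over the list alone. Thymidine kinase Tk1 rose by 1.70 (SE 0.18, adjusted p = 0.009), the ribonucleotide reductase subunit Rrm2 by 1.79 (SE 0.23, adjusted p = 0.0176), and the replicative helicase genes Gins1 and Mcm5 by 1.58 (SE 0.22, adjusted p = 0.024) and 1.15 (SE 0.17, adjusted p = 0.0279). Of 63 tested genes of mitosis, 15 rose, 1 fell and 47 did not pass, and 41 rose and 1 fell when adjusted over the list alone. Ccna2 rose by 1.95 (SE 0.16, adjusted p = 0.00347), Mki67 by 1.73 (SE 0.17, adjusted p = 0.00783), Ckap2l by 1.70 (SE 0.20, adjusted p = 0.0136) and Espl1, the protease that releases sister chromatids, by 1.47 (SE 0.18, adjusted p = 0.0162). The one member that fell was Pttg1, which encodes securin, the inhibitor of that protease (log2 difference −1.22, SE 0.17, adjusted p = 0.0251). It was named after its values were seen, and it is among the 100 tested genes nearest to Irgm1 in chromosome order. Every gene named here but Ccna2 and Pttg1, which was not followed through the alternatives, lost the call without wild-type replicate 2, where the counts were lowest, and with any 1 array left out their adjusted p reached at most 0.12, for Mcm5.

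The mean differences of the 2 lists were 0.76 (camera adjusted p = 7.82e-21) and 0.85 (camera adjusted p = 5.0e-22). With an estimated correlation the adjusted p of either was 0.0836, and by fry 0.00555. Without knockout-labelled replicate 3 the means were 0.75 and 0.92. On the 3 knockout-labelled arrays the T and NK cell markers (mean 2.24) and the 5' probe set of the 18S ribosomal RNA control (by 1.74, with no overlap) were also higher. Ribosome biogenesis and Myc targets had a mean difference of 0.21 over 36 tested genes (camera adjusted p = 0.00444, 0.345 with an estimated correlation) and oxidative phosphorylation a mean of 0.16 over 60 (camera adjusted p = 0.00147, 0.366 with an estimated correlation). Neither passed by fry (0.0813 and 0.125) or with no filter on dim probe sets (0.0667 and 0.0631). Limma called 0 members of either list, also when adjusted over the list alone. The smallest p in these lists belonged to Nolc1 (0.42, unadjusted p = 0.0201, adjusted p = 0.218) and Atp5pb (0.46, unadjusted p = 0.00372, adjusted p = 0.112).

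**Figure D2:**
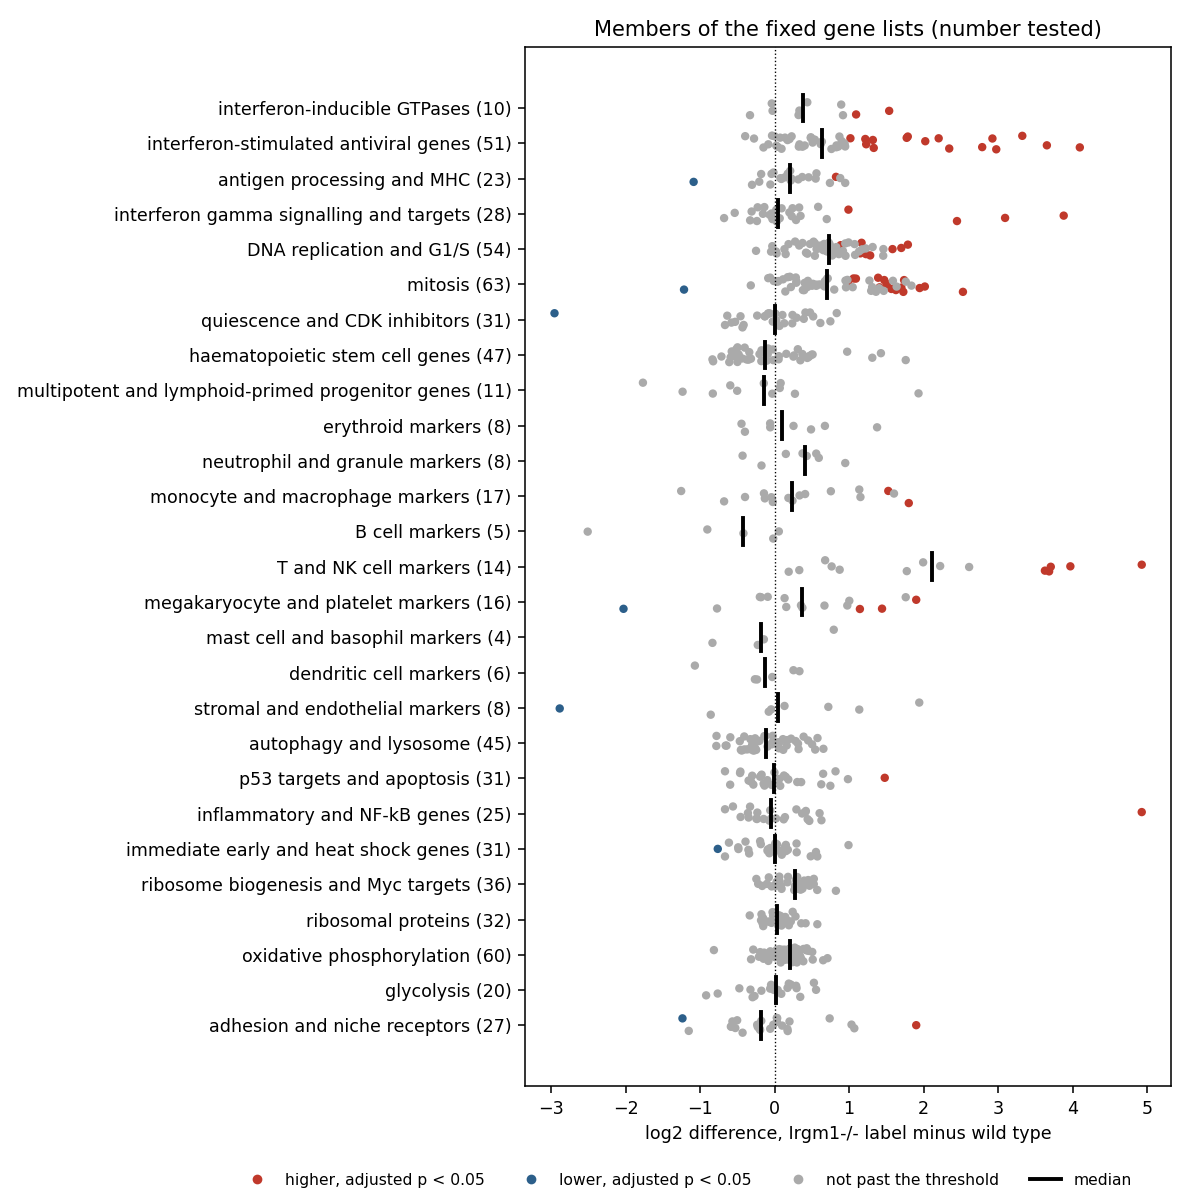
Log2 differences, arrays labelled Irgm1−/− minus wild type, of the tested members of each gene list on the x axis, 1 dot per gene, with the list on the y axis and its median as a black bar. Genes past adjusted p of 0.05 are red (higher) or blue (lower). The lists of antiviral genes (mean 0.97), DNA replication (0.76), mitosis (0.85) and T and NK cell markers (2.24) lie to the right of 0, and the stem cell list (mean −0.03) straddles it.

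Stem cell genes went in both directions. Of 47 tested haematopoietic stem cell genes, 0 rose and 0 fell in the limma fit, and 4 rose and 5 fell when adjusted over the list alone. The smallest p belonged to the efflux pump Abcb1b (0.97, SE 0.19, adjusted p = 0.0651), the transcription factor Gata2 (−0.83, SE 0.17, adjusted p = 0.0664), the aldehyde dehydrogenase Aldh1a1 (1.31, SE 0.26, adjusted p = 0.0681) and Hoxa9 (−0.48, SE 0.10, adjusted p = 0.0774). The median was −0.13 and the mean −0.03 (camera adjusted p = 0.196). The mean was 0.01 without knockout-labelled replicate 1 and 0.02 without wild-type replicate 2, and without wild-type replicate 3 it was −0.11 (camera adjusted p = 0.0481, against a range of 0.000889 to 0.594 over the alternatives). Of 31 tested genes of quiescence and CDK inhibitors 1 fell, Ndn, an imprinted gene that restrains the cell cycle (log2 difference −2.95, SE 0.27, adjusted p = 0.00533). It was also the only member past the threshold when adjusted over the list alone. The CDK inhibitor Cdkn1c differed by −0.63 (SE 0.17, adjusted p = 0.143). That list had a median of 0.01, a mean of −0.07 and a downward test (camera adjusted p = 0.493). Of 11 multipotent and lymphoid-primed progenitor genes 0 passed by the probe set that represented each, and 1 rose and 3 fell when adjusted over the list alone. The list's mean was −0.25 (camera adjusted p = 0.221). With a filter at the 70th percentile it was −0.76 (camera adjusted p = 0.00824, within a range that reached 0.626). Flt3 was at −1.23 (SE 0.27, adjusted p = 0.0915) and Cd48 at 1.93 (SE 0.44, adjusted p = 0.101). Satb1 was at −1.77 (SE 0.39, adjusted p = 0.0913), and of its 4 other tested probe sets 1 was called lower and 1 had the opposite sign.

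Markers of T and NK cells, types that lineage staining is commonly used to exclude, were also higher. Of 14 tested, 5 rose, 0 fell and 9 did not pass, and 8 rose when adjusted over the list alone. These were Ccl5, the NK receptor subunit Klrd1 (3.97, SE 0.62, adjusted p = 0.0342), Ms4a4b (3.71, SE 0.51, adjusted p = 0.024), granzyme B (Gzmb, 3.69, SE 0.46, adjusted p = 0.0162) and Thy1 (3.63, SE 0.48, adjusted p = 0.0209). Ccl5 was high on each knockout-labelled array (12.81, 12.77 and 13.52). The T cell receptor genes were highest on knockout-labelled replicate 3. Cd3g was at 4.15, 3.32 and 7.06 on the knockout-labelled arrays against 2.90 ± 0.02 (SD, n = 3) in wild type, and Cd3d at 4.56, 3.45 and 6.92 against 2.46 ± 0.03 (SD, n = 3). The list passed (camera adjusted p = 8.27e-10) with an adjusted p of 0.346 with an estimated correlation and 0.0893 by fry. Its 14 members were those of 27 on the array that passed the filter on dim probe sets, which a rise on the 3 knockout-labelled arrays alone can meet. The mean was 1.51 with no filter, 1.77 with a filter at the 25th percentile, 3.20 at the 70th percentile and 1.68 without knockout-labelled replicate 3. Klrd1 and Gzmb lost the call without knockout-labelled replicate 1 or any 1 wild-type array, Ms4a4b without knockout-labelled replicate 1 or wild-type replicate 1 or 2, and Thy1 without knockout-labelled replicate 2 or any 1 wild-type array, with adjusted p of up to 0.134, 0.0839, 0.0969 and 0.0973.

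Other blood and stromal markers moved in both directions. Of 16 megakaryocyte and platelet markers, 3 rose and 1 fell, and 7 rose and 2 fell when adjusted over the list alone. P-selectin (Selp), a platelet and endothelial adhesion receptor, rose by 1.90 (SE 0.23, adjusted p = 0.0135), and Mmrn1, a carrier of factor V, fell by 2.03 (SE 0.23, adjusted p = 0.0122). The list's mean was 0.42 (camera adjusted p = 0.0179, 0.294 with an estimated correlation and 0.0203 by fry), and did not pass without knockout-labelled replicate 2 (0.38, camera adjusted p = 0.0661), with no filter (0.30, 0.0922) or with a filter at the 25th percentile (0.34, 0.0537), within a range that reached 0.294. Of 17 monocyte and macrophage markers 2 rose, Ms4a6b (1.80, SE 0.28, adjusted p = 0.0338) and Ms4a6c (1.53, SE 0.23, adjusted p = 0.0313), and 5 rose and 1 fell when adjusted over the list alone. Cd14 differed by −1.25 (SE 0.23, adjusted p = 0.0518), and the list did not pass (mean 0.38, camera adjusted p = 0.19). Without wild-type replicate 1 it did (mean 0.64, camera adjusted p = 0.00148), within a range that reached 0.594 with an estimated correlation, and by fry it did not pass (0.355). Selp lost the call without knockout-labelled replicate 1 or wild-type replicate 1 or 2, Mmrn1 without wild-type replicate 1 or 2, Ms4a6b without knockout-labelled replicate 2 or any 1 wild-type array and Ms4a6c without any 1 array, with adjusted p of up to 0.0811, 0.0696, 0.131 and 0.12. Of 8 stromal and endothelial markers 1 fell, the collagen gene Col1a2 (−2.88, SE 0.30, adjusted p = 0.00889), with 2 higher and 2 lower when adjusted over the list alone. The lists of erythroid (mean 0.23, camera adjusted p = 0.38), neutrophil (0.31, 0.221), B cell (−0.76, 0.369), dendritic cell (−0.17, 0.735) and stromal markers (0.01, 0.993) did not pass, and limma called 0 members of the first 4 of these. With no filter on dim probe sets the B cell list passed downward (mean −0.42, camera adjusted p = 0.00683, within a range that reached 0.846). Wild-type replicate 1 stood apart in that list, with Fcer2a at 6.83 there against 4.17 and 4.19 on the other wild-type arrays and Ighm at 12.73 against a wild-type mean of 9.92, and without it the list's mean was −0.21. Of those, 2 erythroid members rose and 1 fell when adjusted over the list alone, and 0 of the other 3 lists. The 4 mast cell and basophil markers had a median of −0.18, and 1 rose and 1 fell when adjusted over the list alone.

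Of the 10 largest falls, 4 were of imprinted genes, with Meg3 the largest. Besides Meg3, for which 4 of 6 other tested probe sets were called in the same direction and 0 had the opposite sign, Rian, a noncoding RNA of the same imprinted cluster, fell to the level of the control probe sets and was at least 6.36-fold lower (adjusted p = 0.000548). The 1 other tested probe set of Rian had the same sign and was not called. Peg3, a zinc-finger gene expressed from the paternal allele, was at least 7.48-fold lower (adjusted p = 0.0208), and Ndn was 7.75-fold lower. The others were the neurotrophin gene Ntf5 (−3.82, SE 0.28, adjusted p = 0.00207), Dcstamp (−3.42, SE 0.34, adjusted p = 0.00737), Rnf208 (−3.36, SE 0.36, adjusted p = 0.009), the pseudokinase gene Trib2 (−3.35, SE 0.27, adjusted p = 0.00317), the pyrimidine-degrading enzyme Dpys (−3.34, SE 0.37, adjusted p = 0.0112) and Col1a2. Meg3 was 4.41, 4.93 and 5.84 on the knockout-labelled arrays and between 10.73 and 10.85 on the wild-type arrays. Peg3 lost the call without knockout-labelled replicate 1 or 2 or wild-type replicate 1 or 2, Dpys without knockout-labelled replicate 1 or wild-type replicate 2, Rnf208 without wild-type replicate 1 or 2, and Dcstamp and Col1a2 without wild-type replicate 2, with adjusted p of up to 0.0969 for Peg3 and less for the others.

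The remaining lists did not pass with the filter at the array median. Autophagy and lysosome genes, a process in which Irgm1 takes part, had 0 of 45 members called by limma and 1 lower when adjusted over the list alone, with a mean of −0.09 (camera adjusted p = 0.218). It passed downward with no filter on dim probe sets (mean −0.10, camera adjusted p = 0.00106) and with a filter at the 25th percentile (−0.10, 0.0186), within a range that reached 0.594. Its smallest p belonged to Gabarapl1 (−0.78, SE 0.15, adjusted p = 0.061). Among 31 p53 targets and apoptosis genes the proapoptotic Pmaip1 rose by 1.48 (SE 0.26, adjusted p = 0.0454), and 2 rose when adjusted over the list alone. That list had a median of −0.00112 and a mean of 0.07 (camera adjusted p = 0.845). Ccl5 was the only 1 of 25 inflammatory and NF-kB genes to rise, in either adjustment, and the list had a median of −0.05 and a mean of 0.20 (camera adjusted p = 0.959). Zfp36, a decay factor of inflammatory mRNAs, was the only 1 of 31 immediate early and heat shock genes to fall, in either adjustment (−0.76, SE 0.13, adjusted p = 0.0397), in a list with a median of 0.01 and a mean of −0.02 (camera adjusted p = 0.612). Ribosomal proteins (0 of 32 called, 1 higher when adjusted over the list alone, mean 0.06, camera adjusted p = 0.38) and glycolysis (0 of 20 called, 1 lower when adjusted over the list alone, median 0.02, mean −0.03, camera adjusted p = 0.935) did not pass. Of 27 adhesion and niche receptors Selp rose and S1pr1, the receptor through which cells leave tissues along a lipid gradient, fell by 1.24 (SE 0.22, adjusted p = 0.0498), with 2 higher and 2 lower when adjusted over the list alone (mean −0.05, camera adjusted p = 0.38). Pmaip1 and Zfp36 lost the call without any 1 array and S1pr1 without any 1 but wild-type replicate 3, with adjusted p of up to 0.158, 0.148 and 0.175.

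Transcripts of both sexes were present on each array. Xist, expressed from the inactive X chromosome, was at 14.51 ± 0.23 on the knockout-labelled arrays and 14.61 ± 0.27 on the wild-type arrays, and the Y-linked Eif2s3y at 10.02 ± 0.62 and 9.83 ± 0.58 (SD, n = 3 each). Neither differed between the groups by more than the spread (adjusted p = 0.814 and 0.848). On single arrays Xist lay between 14.26 and 14.81 and Eif2s3y between 9.26 and 10.62, so no array lacked either transcript. Another probe set of Eif2s3y was at the control level on each array (2.76 to 2.92). Each array may thus have held RNA of male and female mice together, which the labels do not state and which was not tested.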

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

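The 5' probe set of the mouse 18S ribosomal RNA control, which took no part in the comparison, read 11.91 ± 0.65 on the arrays labelled Irgm1−/− and 10.17 ± 0.93 on the wild-type arrays (SD, n = 3 each), higher by 1.74 with no overlap between the groups. It was the 1 of 19 control probe sets for mouse transcripts with a difference of means over 1 log2 unit and every knockout-labelled array above every wild-type array, the closest pair being 11.20 and 11.15.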

How the results depend on the processing

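The fit with the actin gap as a covariate was chosen after the data were seen, and the cause of the changes below was not tested except where stated. None of the 45 called genes of the naming rule changed direction in any alternative, and 581 of their 754 values stayed past the threshold. Over all named genes, 1747 values kept their direction and their side of the threshold, 173 passed no longer and 34 passed newly. Against 150 probe sets higher and 163 lower, the counts were 49 and 54 with no filter and 62 and 64 with a filter at the 25th percentile, both with more dim probe sets in the adjustment. They were 401 and 463 with array weights, 252 and 263 with the actin gap, and 314 and 315 at adjusted p under 0.1. With 1 array left out, which leaves fewer arrays, they ranged from 17 to 138 and from 28 to 129. The values gave no sign that the replicate numbers paired the arrays. Same-numbered arrays had residual correlations of −0.109, −0.018 and −0.276, and differently numbered ones ranged from −0.20 to 0.239. Residuals around means of 3 arrays constrain each other, so these correlations cannot exclude a pairing. The replicate block, which also costs degrees of freedom, gave counts of 27 and 41. With the block the MHC list had a mean of 0.21 (adjusted p = 0.053), and no other list given most room changed its call. That list also missed the threshold with no filter (0.21), a filter at the 25th percentile (0.21) or on the mean over 6 arrays (0.21), no intensity trend (0.21), array weights (0.18), the actin gap (0.18), an estimated correlation and fry (0.21 each), and ranged from 0.12 to 0.31 with 1 array left out. An estimated correlation ended the calls of the GTPases (0.51), the antiviral genes (0.97), DNA replication (0.76) and mitosis (0.85), and fry that of the GTPases (0.51), by construction through the test alone. With 1 array left out, the GTPases ranged from 0.36 to 0.66, interferon gamma targets from 0.28 to 0.44 and stem cell genes from −0.11 to 0.0239. Interferon gamma targets passed with the mean of the probe sets of a gene (0.39). Stem cell genes passed with no filter and with a filter at the 25th percentile (−0.0351 each) and had the opposite sign with the mean of the probe sets of a gene (0.00702). Other means near 0 also changed sign. Dendritic cell markers were at 0.0173 with a filter at the 25th percentile. Stromal markers were at −0.0049 after quantile normalisation, −0.15 with array weights and −0.0541 with the actin gap. With the mean of the probe sets of a gene, immediate early genes were at 0.00647 and glycolysis at 0.0155, and immediate early genes were at 0.00633 without probe sets of shared sequence. Lmo4 was at 0.0564 with array weights. With 1 array left out, stromal markers ranged from −0.14 to 0.15, immediate early genes from −0.0807 to 0.0384, glycolysis from −0.11 to 0.0505, Lmo4 from −0.35 to 0.0256, Csf2rb from −0.43 to 0.0327, Ms4a1 from −0.0111 to 0.14, Xist from −0.26 to 0.0278, Eif2s3y from −0.11 to 0.51 and Kdm5d from −0.0936 to 0.21, none of them called. The control level, 3.00 to 3.18, limits the folds of genes that fall to it.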

Other observations

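Of the tests below, those of admixed T cells, of progenitors and of stem cell loss were chosen after the values were seen, as were the added lists of imprinted, T cell receptor and NK receptor genes and the genes named in the next paragraph.

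Further genes passed the threshold outside the rule for naming genes. They were not followed through the alternatives, so whether their calls hold with an array left out is not known. Where called probe sets are counted, probe sets of the same gene that were not called are left out. Socs2, a feedback inhibitor of cytokine signalling, rose by all 4 called probe sets, from 1.54 to 2.14 on the log2 scale, and 1 of them moved from 9.02 to 11.01 (log2, SE 0.26, adjusted p = 0.0197 in the limma fit). Irf7, a transcription factor that amplifies type I interferon, rose by 2.20 on the log2 scale (adjusted p = 0.0313). The maintenance DNA methyltransferase Dnmt1 rose from 11.02 to 12.02 (adjusted p = 0.0261) and the repair gene Brca1 2.04-fold (adjusted p = 0.0393). The inhibitors of differentiation Id2 and Id3 rose 2.91-fold and 3.01-fold (adjusted p = 0.038 and 0.0313), and the junction protein gene Tjp1 rose 7.92-fold, from 7.10 to 10.08 (adjusted p = 0.000548). Among the falls were the progesterone receptor Pgr (−1.50 and −2.21 by its called probe sets) and the growth factor receptor Igf1r, which fell from 10.04 to 8.77 (adjusted p = 0.0448).

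Imprinted genes beyond the 4 among the largest falls were also lower on the arrays labelled Irgm1−/−. Of 28 tested genes on a list written after Meg3, Rian, Peg3, Ndn, Igf2, Zdbf2 and Airn had been seen, those 7 fell, 24 had a negative difference, and the list's median was −0.51. Loss of stem cells from the sorted gate stays open. The stem cell list had a median of −0.13 (95% bootstrap interval over members −0.35 to 0.05), far from the several-fold falls of Meg3 and Ndn. The bound for that median was set after the values were seen, so it cannot decide. With no filter on dim probe sets the stem cell list passed downward (camera adjusted p = 0.000889). Its mean was −0.0351 there and −0.03 with the filter, so the pass did not come from a larger fall of its members. Whether the fall is confined to a few loci stays open, because the 21 members not seen beforehand had a median of −0.17, with 0 called by limma (camera p = 0.00647, and p = 0.0406 with an estimated correlation), and so does a part played by dim probe sets, since the 14 members with a wild-type mean over 8 had a median of −0.22 and 2 called falls. A shared change in imprinted expression may underlie the pattern, as a hypothesis, and no biological explanation was tested beyond the genotype label.

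Of 14 markers of T and NK cells, 5 rose beside the interferon-stimulated genes. On knockout-labelled replicate 3 the T cell receptor genes lay a median of 1.55 above the wild-type mean, which is consistent with T cells or their RNA in that sample, although the sort stained for lineage antigens. On replicates 1 and 2 the median was 0.0607. Among its genes, Cd3d, Cd3e and Cd3g lay above every wild-type array there, and Lat and Cd247 below the wild-type mean. Zap70 was at the control level in both groups, so its value does not count either way. On these replicates Cd3d was at 4.56 and 3.45 against 2.46 in wild type, and Ccl5 was at 12.81 and 12.77. A small share of T cells there thus cannot be told apart from expression of Ccl5, Gzmb and Thy1 by the sorted cells. NK cells stay open too, since the NK receptor genes had a median of 0.28, under the bound set beforehand, but that list did not hold the called gene Klrd1, its members Prf1 and Ncr1 were at the control level in both groups, and Klrc1 (4.75, 5.82 and 6.80 against 4.25 ± 0.03 in wild type, SD, n = 3) was higher with no overlap, while Klrk1 (2.55, 2.85 and 6.13) was above the control level on replicate 3 alone. A response of the stem cells themselves remains an untested hypothesis.

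Of the cell cycle genes, 8 of 54 for DNA replication and 15 of 63 for mitosis rose and Pttg1 fell, and neither list passed with an estimated correlation (adjusted p = 0.0836). T cells stay open, because without knockout-labelled replicate 3, where T cell receptor genes were highest, the mean of the cell cycle lists was 1.04 times its value with that array, but the T and NK cell markers also kept a mean of 1.68 of their 2.24. Coverage of the amplified RNA as read by the actin gap did not separate the groups, whose gaps overlapped. In the fit with that gap the mean of the cell cycle lists was 1.03 times the original. With so balanced a gap that fit could move the mean little, so it adds nothing to the overlap. The 5' probe set of the 18S control was higher by 1.74 with no overlap, so another difference in the RNA stays open. Multipotent or lymphoid-primed progenitors stay open, because the 11 members of their list went both ways (median −0.14, with Cd48 at 1.93, Flt3 at −1.23 and Satb1 at −1.77), although with a filter at the 70th percentile the list passed downward (mean −0.76, adjusted p = 0.00824, within a range that reached 0.626). Of the 4 other tested probe sets of Satb1, 1 was called lower and 1 had the opposite sign. A higher share of cycling stem cells stays open as well, as a hypothesis that expression alone did not test.

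The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 150 probe sets higher and 163 lower and the highest other split 1 and 0, so that 1 of the 10 splits gave as many in either direction. The number of gene lists that passed was 9 in the real split and 10 in the highest other, and 2 of the 10 splits passed as many, so the count of passing lists did not stand apart from other groupings. The other splits mix the groups and keep part of any difference between them. Lists that pass in them, and their list means, thus do not show what would arise without a difference. The mean of the antiviral list was 0.97 against a largest size of 0.56 in the other splits, that of mitosis 0.85 against 0.41, that of the GTPases 0.51 against 0.48 and that of the MHC list 0.21 against 0.32.

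Of the 100 tested genes nearest to Irgm1 in chromosome order, 50 on each side, 3 were called (Hmmr, Pttg1 and Zfp354a, named after their values were seen), against 208 of 10273 elsewhere (2.03%), with a 2-sided Fisher's exact test p of 0.46. Pttg1 was the mitosis gene that fell, and Zfp354a fell 4.21-fold (adjusted p = 0.00385 in the limma fit). With so few calls the test cannot decide whether either fall belongs to a place near Irgm1.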
